A study of Homo sapiens with 21 samples.

How the data were processed

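RNA was extracted from mammary tumors, cell suspensions and brain metastases of 2 xenograft models with the Qiagen RNeasy Mini Kit, and libraries were made with the KAPA Stranded mRNA-Seq Kit, per the labels' protocols. The submitters' processing notes name STAR 2.5.2b, Salmon 0.8.2 and the builds GRCh38 and GRCm38. The order and role of these tools, the transcript annotation and any trimming or filter are not given in the sources used here. The authors deposited 1 Salmon table per library with 198442 human and 123063 mouse transcripts. Per the file headers each row holds the transcript's length, its effective length, transcript abundance (TPM) and the estimated count of reads. In the deposited files TPM sums to 1000000 over both species together, so it moves with the share of mouse transcripts and was not used for tests. Estimated counts in the deposited files are expected counts that need not be whole, since Salmon divides a read that fits several transcripts among them. Reads that fit a human and a mouse transcript alike, or near-identical paralogs, were divided in this way too, and levels of such genes are uncertain.

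Human transcripts were matched by identifier to GENCODE release 29 (GRCh38), which supplied gene symbols and 1-based coordinates. Of the human transcripts 193967 matched, and they held 99.57 to 99.72% of human counts. Estimated counts were summed per gene over 57239 genes and rounded to whole numbers. No table that joins mouse transcripts to genes was used, so mouse transcripts entered only as a share of all counts, with 95% Wilson intervals. Before the tests 1221 genes were left out, and genes whose level may follow the genome of 1 donor are not named. The depth per library, 3.15 to 17.11 M human counts (M, 1000000 counts), sets the floor for genes without counts. A fold against a group without a count was computed against 3 counts over that group and is given as "at least". Counting error is the only error such floors and intervals cover.

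Samples were grouped by model and by tumor, day 0, day 7 or brain, from the labels. Gene counts of all 21 libraries were fitted together in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with 1 coefficient per group, TMM scaling and the filterByExpr filter, which left 18936 genes. The quasi-likelihood test was used with Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p under 0.05 are the calls. One fit over all libraries was chosen so that the groups with 1 or 2 libraries share an estimate of the spread, which assumes that they vary like the others. The common biological coefficient of variation (BCV) was 0.369, with 13 residual degrees of freedom and a median of 2.59 prior degrees of freedom. There were 12 comparisons of groups and 3 tests of whether a change differed between the models. P-values set each change against the spread between libraries within groups, pooled over all groups. They do not measure the spread between mice of the compared groups alone.

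Before the data were examined, 33 gene lists were fixed, for pathways and for cell types that tumor, suspension or brain could hold. Of these 32 had at least 5 tested members, which makes 480 list tests. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. List members were also adjusted over the list alone. List means are averages of log2(CPM + 1) over members. Also before the data were examined, the genes to be named were set by rule. They are the 10 protein-coding genes with the largest fold change in each direction among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries, and up to 4 called members of each list in order of adjusted p. With 3 libraries against 3, chance leaves 10% of genes without overlap. The text gives part of the genes so chosen.

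Replicate numbers pair samples where the labels give the same mouse, which holds for WHIM2 tumor, day 0 and day 7 and for WHIM30 day 0 and day 7. Deviations from the group means correlated between day 0 and day 7 of one mouse at 0.895, 0.724 and 0.557 in WHIM30 (replicates 1 to 3). Between replicates 2 and 3 they correlated as well, at 0.565 and 0.723, and between replicate 1 and these at -0.816 to -0.617, so the values follow replicate 1 against the rest and not each mouse. In WHIM2 the correlations between libraries of one mouse lay between -0.023 and 0.048. The labels decide the pairing, and fits with the mouse as a block were made as an alternative on the libraries that share mice. Sequencing lanes, read from the names of the deposited files, were unevenly spread. Only the lane number was read, and whether libraries with the same number shared a sequencing run was not checked. WHIM2 libraries ran in lane 5 except day 0 replicate 3 and the brain metastasis (lane 6), WHIM30 tumors ran in lane 5, WHIM30 suspensions in lane 6 and WHIM30 brain metastases in lanes 2 and 3.

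Alternatives changed 1 choice at a time, except the block, whose fits also dropped the libraries that share no mouse. They were RLE and upper quartile scaling, DESeq2 1.42.0, other filters on low counts, an offset for the average effective transcript length, protein-coding genes alone, a minimum absolute log2 fold change of 1, a fit on the compared groups alone, each library left out in turn and the mouse as a block. Added after the data were seen were fits without 4 WHIM30 suspension libraries, fits on one model alone, fits within a lane and fits on the libraries of the block fits without the block. Medians of all log2 fold changes lay between 0.08 and 0.15 in the comparisons of models. They moved by about 0.1 at most with another scaling, for example from 0.13 to 0.23 at day 0 with upper quartile scaling.

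The tests were checked on simulated counts drawn from the means and library sizes of the real genes, with 200 of 18936 genes changed. Changed genes had a mean of at least 1 CPM, and all others kept the same mean in every group. In the real data the comparisons simulated without a block called 798 to 9764 genes. With so many fewer changes the adjustment is stricter, so the recoveries below do not give the power of the real comparisons. In the simulated WHIM2 day 0 against tumor comparison edgeR recovered 30% of 2-fold and 72% of 4-fold changes with 5 false calls. It recovered 27% and 70% for WHIM30 day 0 against tumor and 23% and 68% for WHIM30 brain against tumor. Recovery was 10% and 57% for the lone WHIM2 brain library against tumors and 31% and 72% between the tumors of the models. These simulations gave 1 to 6 false calls with edgeR and 29 to 50 with DESeq2. The block was tried on other simulated counts, with a mouse effect added and only the WHIM2 tumor and suspension libraries. It recovered 3% and 46% there with 2 false calls, which cannot be set against the values without a block. Simulated groups vary alike, which the WHIM30 suspensions and brain libraries do not. The BCV was 0.519 between the WHIM30 brain libraries and 0.074 to 0.095 between WHIM30 tumors. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Some genes of the lists are not reported here by name.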

Results

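RNA sequencing was used to measure transcripts in WHIM2 and WHIM30, 2 patient-derived xenograft (PDX) models labelled as triple-negative, basal-like breast cancer. In a PDX, human tumor tissue is carried in immunodeficient mice, here of the NSG strain, so each library holds human transcripts and transcripts of the mouse host. The 21 libraries fell into 8 groups. Each model had 3 libraries of mammary tumor tissue, 3 of cell suspensions prepared from such tumors and collected at once (day 0), and 3 of suspensions collected after 7 days in culture (day 7). Brain metastases, which arose after injection of cells into the heart, gave 1 library for WHIM2 and 2 for WHIM30. Libraries of one group came from different mice. WHIM2 tumor, day 0 and day 7 libraries shared 3 mice, WHIM30 day 0 and day 7 libraries shared 3 others, and the WHIM30 tumors and all brain metastases came from further animals. The design addresses how the models differ in expression, and how suspensions and brain metastases differ from mammary tumors within a model.

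Total depth ranged from 11.93 to 24.75 M estimated counts per library (M, 1000000 counts), of which 3.15 to 17.11 M lay on human transcripts. Human depth was 12.2 to 16.45 M in WHIM2 tumors, 13.98 to 16.04 M at day 0, 15.28 to 16.64 M at day 7 and 9.64 M in the WHIM2 brain metastasis. In WHIM30 it was 12.96 to 14.86 M in tumors, 9.72 to 12.28 M at day 0, 11.31 to 17.11 M at day 7, and 3.15 and 12.65 M in brain replicates 1 and 2. Mouse transcripts took 4.85% ± 2.10 of counts in WHIM2 tumors, 3.11% ± 0.24 at day 0 and 3.03% ± 0.14 at day 7 (SD, n = 3 each). They took 8.02% ± 0.28 in WHIM30 tumors, 16.4% ± 3.27 at day 0 and 19.2% ± 10.1 at day 7 (SD, n = 3 each). The share was 44.9% in the WHIM2 brain metastasis and 78.9% and 18.9% in those of WHIM30. The 95% Wilson interval of any one library's share was at most 0.023 percentage points to either side. Such intervals, and the floors behind the bounds given for genes without counts, cover counting error only. Below, log2 fold changes carry a standard error (SE) derived from the test's F statistic. It is the absolute log2 fold change over the square root of F. Where a group holds few counts, such an SE need not cover the counting error of that group. Expression is in counts per 1000000 human counts after TMM scaling of the library sizes (CPM, mean ± SD). Adjusted p-values come from edgeR's quasi-likelihood test over 18936 genes unless another test is named.

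**Figure D1:**
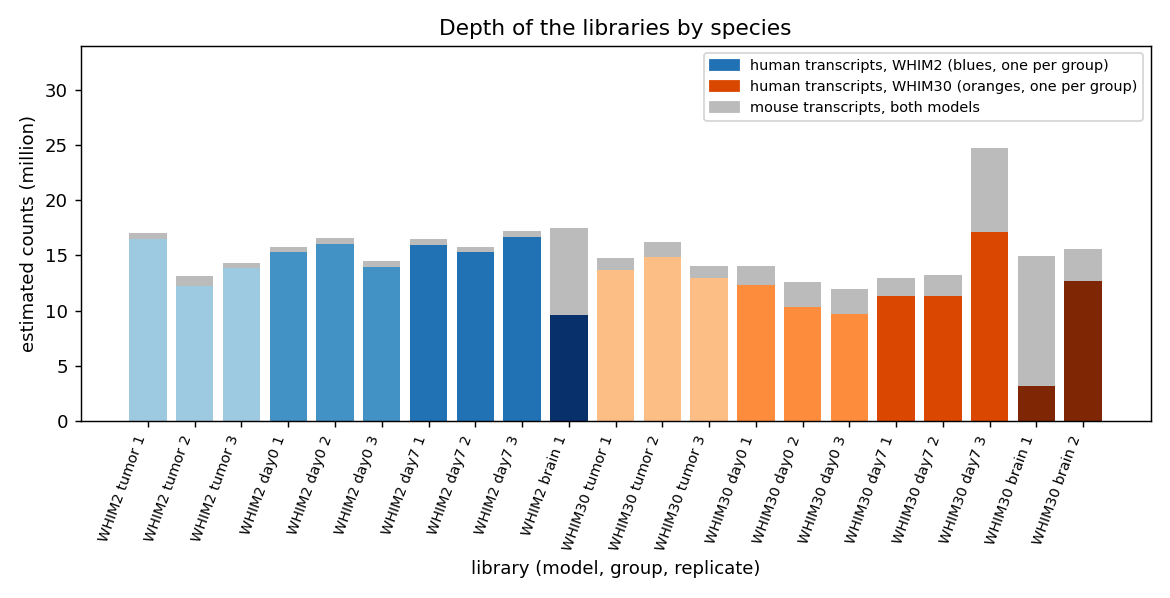
Bars give the estimated counts of each library in M (1000000 counts, y axis), with human transcripts in blue for WHIM2 and orange for WHIM30 and mouse transcripts in grey, and 1 bar per library (x axis). Mouse counts make up 78.9% of WHIM30 brain replicate 1 and 44.9% of the WHIM2 brain library.

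Principal component analysis separated the models along the first component (61.3% of the variance). WHIM2 libraries lay between -135 and -123.6 on it and WHIM30 libraries between 33.7 and 179. WHIM2 suspensions stood apart from WHIM2 tumors on the third component (9.8%), at 60.2 to 61.8 against -88.8 to -86.5. The second component (14.5%) divided the WHIM30 suspensions. Those of replicate 1 lay at 84.3 (day 0) and 82.4 (day 7), within the range of the WHIM30 tumors (80.2 to 86.9). The 4 libraries of the other 2 host mice, replicates 2 and 3, lay between -102.7 and -92.6. The day 0 libraries of these mice differed by a BCV of 0.045, less than any pair of WHIM30 tumors (0.074 to 0.095). Whether they were separate preparations of one pool was not tested. A list of epithelial junction genes, which hold epithelial cells together, averaged 6.36 to 6.54 (log2 of CPM + 1, averaged over members) in the WHIM30 tumors and 6.52 in both replicate 1 suspensions, but 2.16, 2.2, 2.23 and 1.96 in the 4 others. A fibroblast list, mainly extracellular matrix genes, averaged 5.53 to 6.29 in the tumors, 5.47 in both replicate 1 suspensions and 7.29 to 8.88 in the 4 others. Mouse transcripts took 12.7% and 12.4% of counts in the replicate 1 suspensions and 18.0%, 18.6%, 14.4% and 30.9% in the 4 others. Counts of genes in comparisons with WHIM30 suspensions are therefore also given without these 4 libraries, an alternative added after the data were seen. It leaves 1 WHIM30 suspension per time, with the spread taken from the other groups.

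**Figure D2:**
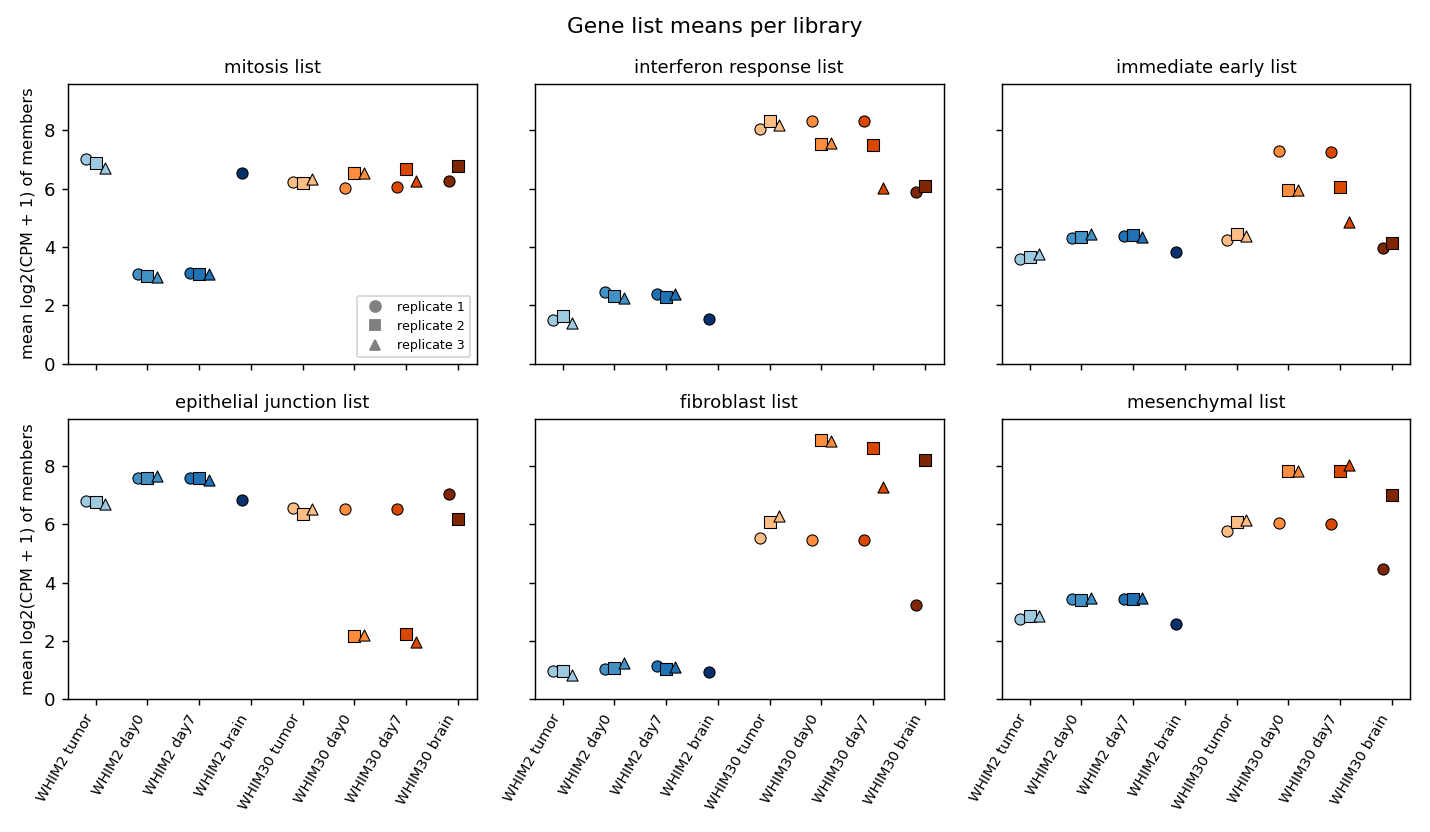
Each panel plots the mean log2(CPM + 1) of one gene list (y axis) in every library, by group (x axis), with the marker shape giving the replicate number and the color the group. The mitosis list lies between 2.98 and 3.1 in WHIM2 suspensions and above 6 in every other library, and the epithelial junction list lies between 1.96 and 2.23 in 4 WHIM30 suspensions and above 6 elsewhere.

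Mammary tumors of the models differed in interferon-response genes. All 32 measured members of that list were higher in WHIM30 (32 of 32 also when adjusted over the list alone), with a median log2 fold change of 8.76. OAS2, a sensor of double-stranded RNA (chromosome 12, 112978395 to 113011723, GRCh38), reached 790 ± 67.2 CPM in WHIM30 against 0.0568 in WHIM2 (log2 fold change 13.68, SE 1.16, adjusted p = 1.61e-07). IFI27, another interferon-induced gene, stood at 755 ± 41.5 against 0.108 CPM (12.73, SE 0.95, adjusted p = 3.77e-08). All 13 antigen-processing genes were higher, again 13 when adjusted over the list alone, with a median of 2.41. Among them were NLRC5, the activator of class I genes (6.74, SE 0.4), the immunoproteasome subunit PSMB8 (11.53, SE 0.78) and B2M, the light chain of class I molecules (5.61, SE 0.42). Of 25 NF-kB and cytokine genes 21 were higher and 1, the prostaglandin synthase PTGS2 (-9.35, SE 0.47), was lower, with the same counts adjusted over the list alone and a median of 5.09 (3.44 with genes that lacked counts in a group set to their bound). In competitive tests (camera, correlation preset at 0.01) these lists had adjusted p = 6.52e-35, 1.32e-08 and 8.5e-06. With an estimated correlation none of the 3 was called (adjusted p = 0.267, 0.537 and 0.537 with an estimated correlation).

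Matrix and basal genes were also higher in WHIM30 tumors. FN1, which encodes fibronectin, was higher by 10.9 (SE 0.97), and EFEMP1, a matrix glycoprotein, stood at 834 ± 47.1 CPM (12.56, SE 2.42, adjusted p = 0.000478). The protease inhibitor A2M, without a count in WHIM2 tumors, was at least 2180-fold higher. Of 24 mesenchymal genes 20 were higher (20 adjusted over the list alone; median 4.07, camera adjusted p = 2.3e-05), and of 18 fibroblast genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone; median 8.47, 7.96 with bounds, adjusted p = 0.000367). Among 25 basal keratin and adhesion genes 17 were higher and 1 lower (17 and 1 adjusted over the list alone; median 4.2, adjusted p = 0.000441), led by the desmosomal cadherin DSC3 (8.41, SE 0.68), the growth factor receptor EGFR (2.41, SE 0.22) and the basal transcription factor TP63 (6.42, SE 0.71). WHIM2 tumors in turn had more SOX11, a transcription factor of development (chromosome 2, 5692667 to 5701385), at 244 ± 28 CPM against 0.0613 in WHIM30 (-11.69, SE 0.37, adjusted p = 4.66e-10), and more SCGB3A1, a secretoglobin, at 646 ± 61.9 CPM against 0.32 (-10.93, SE 0.44). Cholesterol synthesis genes were lower in WHIM30 for 13 of 22 members (13 lower and 1 higher adjusted over the list alone; median -1.11, camera adjusted p = 0.000367), among them IDI1 (-3.08, SE 0.24) and FDFT1 (-2.34, SE 0.19). The 13 protein-coding genes of the mitochondrial genome were all lower (13 adjusted over the list alone; median -2.72, adjusted p = 4.75e-05), as were 12 of 25 mitosis genes with 1 higher (12 and 1 adjusted over the list alone; median -0.53, adjusted p = 0.00751). None of these 6 lists was called with an estimated correlation (adjusted p = 0.602, 0.636, 0.602, 0.602, 0.602 and 0.713 with an estimated correlation, in the order given). Over all genes 9764 of 18936 differed, 5297 higher and 4467 lower in WHIM30. All 6 tumor libraries had the same lane number.

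The same question was asked of cell suspensions. In them WHIM30 exceeded WHIM2 in the cell cycle. All 25 mitosis genes were higher in WHIM30 at day 0 and at day 7 (25 each adjusted over the list alone; medians 3.55 and 3.48). The spindle protein NUSAP1 was higher by 3.44 (SE 0.14) and 3.33, the ubiquitin carrier UBE2C by 4.17 and 3.93 and the kinase CDK1 by 3.54 and 3.66. DNA replication genes were higher for 22 of 24 members at each time (22 adjusted over the list alone; medians 2.3 and 2.13), with the replication factor CDC45 higher by 4.36 (SE 0.23) at day 0. Camera gave adjusted p = 9.29e-27 and 1.85e-26 for mitosis and 3.21e-12 and 2.8e-10 for replication, and neither was called with an estimated correlation (adjusted p = 0.131 and 0.127, then 0.415 and 0.546 with an estimated correlation). All 32 interferon-response genes were higher at both times (32 adjusted over the list alone; medians 6.66 and 6.46, camera adjusted p = 3.71e-22 and 8.62e-20; adjusted p = 0.319 and 0.423 with an estimated correlation). Immediate early genes, which respond within minutes to growth factors or stress, were higher for 18 of 26 and lower for 3 at each time (18 and 3, then 19 and 3 adjusted over the list alone; medians 3.07 and 2.78, camera adjusted p = 0.000657 and 0.00266; adjusted p = 0.649 and 0.674 with an estimated correlation). KLF4 (4.25, SE 0.2 at day 0) and FOSB (7.51, SE 0.91 at day 0) were among them. Without the 4 libraries only replicate 1 of WHIM30 is left per time, so list means alone are given for it. At day 0 and day 7 they were 6.01 and 6.07 for mitosis, against 2.98 to 3.1 in WHIM2 suspensions. They were 5.42 and 5.39 against 3.4 to 3.45 for replication, and 8.33 and 8.32 against 2.24 to 2.44 for interferon-response genes. For immediate early genes they were 7.3 and 7.27 against 4.31 to 4.43.

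Matrix genes were among the largest folds between suspensions. COL3A1, a fibrillar collagen, stood at 10400 ± 8570 CPM in WHIM30 against 0.574 in WHIM2 at day 0 (14.16, SE 2.77, adjusted p = 0.000458), and THY1, a surface protein of fibroblasts and other cells, at 631 ± 391 CPM (14.16, SE 1.85, adjusted p = 1.09e-05). The pericyte and fibroblast protein CD248, without counts in WHIM2 at either time, was at least 4760-fold higher at day 0 and at least 3210-fold higher at day 7. Of 18 fibroblast genes 17 were higher at each time (17 adjusted over the list alone; medians 10.82 and 9.63, or 9.8 and 8.93 with bounds; camera adjusted p = 0.000245 and 0.000428; adjusted p = 0.651 and 0.674 with an estimated correlation). The SDs of COL3A1 and THY1 follow the 4 libraries described above. In the other direction SOX11 was at least 1450-fold lower in WHIM30 at day 0 and at least 1770-fold lower at day 7, and the adhesion protein CEACAM5 was at least 433-fold and at least 536-fold lower. Cholesterol synthesis genes were lower for 16 of 22 members with 1 higher at day 0, and for 15 with 1 higher at day 7 (17 and 1, then 15 and 1 adjusted over the list alone; medians -1.37 and -1.25, camera adjusted p = 2.54e-05 and 8.99e-05; adjusted p = 0.562 and 0.546 with an estimated correlation). Epithelial junction genes were lower for 8 of 24 members at day 0 and 9 at day 7 (7 each adjusted over the list alone; median -2.41 at both times, camera adjusted p = 0.00399 and 0.00375; adjusted p = 0.763 and 0.699 with an estimated correlation). Much of that median came from the 4 libraries, without which it was -1.39 and -1.17, with only replicate 1 of WHIM30 left per time. In replicate 1 the fibroblast list mean was 5.47 at both times, against 1.04 to 1.24 in WHIM2 suspensions. The cholesterol synthesis list mean was 5.25 at both times, against 6.54 to 6.58. In all, 11186 genes differed at day 0 (6193 higher, 4993 lower) and 11039 at day 7 (6190 higher, 4849 lower), or 10616 and 10260 without the 4 libraries. Within the one lane that held both models at day 0 (3 libraries against 1) 7100 genes were called, while at day 7 lane and model cannot be told apart.

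Brain metastases of the models (2 libraries against 1) showed some of the same contrasts. Of 32 interferon-response genes 29 were higher in WHIM30 (31 adjusted over the list alone; median 6.24, 6.1 with bounds), IFI44L by 10.2. Of 24 mesenchymal genes 20 were higher (21 adjusted over the list alone; median 5.09, 4.69 with bounds), with FN1 higher by 12.18 (SE 1.79), and of 18 fibroblast genes 13 (14 adjusted over the list alone; median 9.89, 8.67 with bounds). The WHIM30 brain libraries stood far apart in both lists, with means of 4.48 and 6.99 for mesenchymal and 3.22 and 8.22 for fibroblast genes, against 2.59 and 0.93 in WHIM2. FAT1, an atypical cadherin, stood at 377 ± 58.4 CPM in WHIM30 and was at least 1240-fold higher. Heat shock genes, which encode chaperones, were higher for 10 of 18 members (10 adjusted over the list alone; median 1.03), CHORDC1 by 1.99 (SE 0.23) and HSPH1 by 1.6. WHIM2 had 589 CPM of DLK1, a membrane protein of immature cells, which was at least 3220-fold lower in WHIM30, and more SCGB3A1 (-12.0, SE 0.62, adjusted p = 1.13e-08). Cholesterol synthesis genes were lower for 11 of 22 members (11 adjusted over the list alone; median -1.36), FDFT1 by -3.03. Camera gave adjusted p = 2.83e-18 for interferon, 6.76e-05 for mesenchymal, 0.00377 for fibroblast, 0.00377 for heat shock and 5.25e-05 for cholesterol genes (adjusted p = 0.775 for each with an estimated correlation, but 0.924 for fibroblast). The test called 6814 genes, 3582 higher and 3232 lower (52.6% higher, or 46.1% with upper quartile scaling). The lone WHIM2 library was assumed to vary like the other groups, and the 3 libraries lay in different lanes, so lane and model cannot be told apart here.

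Suspensions of WHIM2 cells were then compared with the tumors of the same mice. Genes of cell division fell together. All 25 mitosis genes were lower at day 0 and at day 7 (25 each adjusted over the list alone; medians -4.04 and -4.03), NUSAP1 by -4.45 (SE 0.15, adjusted p = 7.94e-11) and -4.39, the mitotic kinase PLK1 by -4.79 (SE 0.23) and -4.65, and the checkpoint kinase BUB1B by -4.53 and -4.26. All 24 replication genes were lower as well (24 each adjusted over the list alone; medians -2.36 and -2.4). CDC45 fell from 20.6 ± 1.64 to 0.83 ± 0.182 CPM (-4.61, SE 0.24, adjusted p = 2.03e-09), and MYBL2, a transcription factor of the cell cycle, by -5.25 (SE 0.27). The list mean of mitosis genes was 6.71 to 7.01 in the tumors, 2.98 to 3.08 at day 0 and 3.07 to 3.1 at day 7, so the low level was already present in the libraries labelled as collected at once. The camera adjusted p was 4.6e-85 and 5.67e-84 for mitosis and 3.82e-39 and 3.71e-39 for replication. Both lists remained called with an estimated correlation (adjusted p = 0.000916 and 0.000908, then 0.0207 and 0.0199 with an estimated correlation).

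Other gene groups rose in WHIM2 suspensions. Targets of YAP, a transcriptional coactivator of the Hippo pathway, rose for 11 of 17 members at each time (12 and 11 adjusted over the list alone; medians 2.45 and 2.15, the former 2.18 with bounds). They included the Hippo kinase LATS2 (2.18, SE 0.2), the matricellular protein CYR61 (3.17, SE 0.35) and TGFB2 (3.07, SE 0.37), and the list was called with either correlation (camera adjusted p = 4.53e-08 and 2.73e-08; adjusted p = 0.00118 and 0.00103 with an estimated correlation). NF-kB and cytokine genes rose for 17 of 25 members and fell for 1 at each time (17 and 1 adjusted over the list alone; medians 2.1 and 2.57). The inhibitor of apoptosis BIRC3 rose by 4.22 (SE 0.48) and the adhesion molecule ICAM1 by 4.85 (SE 0.6), whereas PTGS2 fell from 415 ± 77 to 49.7 ± 7.87 CPM (-3.06, SE 0.34). Interferon-response genes rose for 16 of 32 members and fell for 1 (16 and 1 adjusted over the list alone at day 0, 17 and 2 at day 7; medians 1.81 and 1.88), IFIT2 by 7.71 (SE 0.92) and SAMD9L by 5.95 (SE 0.85). Antigen-processing genes rose for 6 of 13 members (6 and 7 adjusted over the list alone), and basal keratin and adhesion genes for 8 of 25 (8 each adjusted over the list alone). Camera gave adjusted p = 3.14e-05 and 3.44e-05 for NF-kB, 0.000201 and 0.00016 for interferon, 0.00336 and 0.00282 for antigen processing and 0.0119 and 0.0136 for basal genes. None of these 4 was called with an estimated correlation (adjusted p = 0.394 and 0.411, 0.76 and 0.789, 0.76 and 0.789, 0.76 and 0.789 with an estimated correlation). In a fit on the WHIM2 tumor and suspension libraries alone the basal list was called there, with the mouse as a block (adjusted p = 0.0472 and 0.0467 with an estimated correlation) and without it (adjusted p = 0.019 and 0.0208 with an estimated correlation).

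Among the largest single folds in WHIM2 suspensions were those of genes nearly silent in the tumors. CYP1A1, the cytochrome induced by the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725610), went from no count to 22.5 ± 2.92 CPM at day 0, at least 299-fold higher (adjusted p = 2.09e-05), and was at least 325-fold higher at day 7. IDO1, a tryptophan-degrading enzyme, rose to 22.5 ± 0.734 CPM (8.06, SE 0.69, adjusted p = 4.41e-07) and by 8.21 (SE 0.69) at day 7. The glycoprotein GPNMB rose from 1.08 to 178 ± 16.4 CPM (7.37, SE 0.86), CEACAM5 from 0.129 to 38.6 ± 2.09 CPM (8.15, SE 0.65) and CEACAM6 from 0.459 to 83.3 ± 4.38 CPM (7.54, SE 0.9); the CEACAM genes are close paralogs, and reads they share were split between them by estimation. CLCA2, a regulator of chloride conductance in epithelia, fell from 96 ± 9.83 to 0.346 CPM (-8.08, SE 0.69, adjusted p = 4.52e-07) and by -7.45 (SE 0.66) at day 7. The cytokine IL33 fell from 35 ± 17.2 to 0.243 CPM (-7.11, SE 1.12, adjusted p = 0.000188), and the cell cycle repressor E2F7 by -5.48 (SE 0.77) and -6.16. In all, 5781 genes differed at day 0 (3118 higher, 2663 lower) and 5762 at day 7 (3121 higher, 2641 lower). The share that was higher, 53.9% and 54.2%, was 46.0% and 46.1% with upper quartile scaling. In a fit on the WHIM2 tumor and suspension libraries alone 10332 and 10310 genes were called with the mouse as a block and 10319 and 10293 without it, and on all WHIM2 libraries 10749 and 10694. Within lane 5 alone 4660 were called at day 0, and all libraries of the day 7 comparison ran in that lane.

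Between day 7 and day 0 of WHIM2 no gene changed at an adjusted p under 0.05 by edgeR. At an unadjusted p under 0.05 there were 97 of 18936 genes, far below the share of 0.05 that chance alone gives. The spread pooled over all groups (common BCV 0.369) is wide for these libraries, so small changes can be missed. On the compared groups alone the count of calls was 0 too, with 475 of 14548 genes at an unadjusted p under 0.05. Over all libraries DESeq2 called 3. With the mouse as a block the count was again 0, with 254 genes at an unadjusted p under 0.05. No list had a called member. The suspension libraries of lane 5 were very close. Among these 5, pairs differed by a biological coefficient of variation (BCV) of 0.022 to 0.046, against 0.065 to 0.142 between WHIM2 tumors. Day 0 replicate 3, which ran in lane 6, differed from the 5 by 0.088 to 0.104, within the range of the tumors. Counts of the 5 differed beyond counting noise (chi-square per gene 1.79 to 3.82), so none was counted as a repeat deposit of the same library. Separate preparations of one pool would differ too. Each library was kept as a sample because the labels list it as one.

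In WHIM30 suspensions, immediate early genes rose over the tumors. At day 0, 18 of 26 members rose and at day 7, 13 (22 and 23 adjusted over the list alone; medians 2.44 and 2.47). FOSB, an AP-1 transcription factor (chromosome 19, 45467995 to 45475179), went from 1.01 ± 0.354 to 258 ± 78.9 CPM at day 0 (8.0, SE 0.93, adjusted p = 0.00054) and to 174 ± 154 CPM at day 7 (7.43, SE 0.91, adjusted p = 0.00264). The phosphatase DUSP1 rose by 4.09 (SE 0.32, adjusted p = 2.46e-05) and 3.74, and JUN, a partner of FOS proteins, by 3.83 (SE 0.46) and 3.54. FOS itself rose from 10.9 to 520 ± 369 CPM at day 0 (5.58, SE 1.14). In camera the list had adjusted p = 4.64e-18 and 1.62e-16. It was not called with an estimated correlation (adjusted p = 0.378 and 0.252 with an estimated correlation). Without the 4 libraries only replicate 1 is left per time, so that fit gives no test of the list here. The list mean was 4.25 to 4.43 in the tumors, 7.3 and 7.27 in the replicate 1 suspensions and 4.87 to 6.07 in the 4 others. Heat shock genes rose for 6 of 18 members and fell for 1 at day 0, and rose for 7 at day 7 (7 and 1 each adjusted over the list alone; medians 0.24 and 0.54), with HSPA1B up by 3.9 (SE 0.71) and 3.42, and HSPA6 from 3.28 to 246 ± 178 CPM at day 0 (6.23, SE 1.15, adjusted p = 0.00547). Both have near-identical paralogs, so their own levels are uncertain. The list mean was 7.23 to 7.31 in the tumors, 8.72 and 8.65 in the replicate 1 suspensions, 7.72 to 7.79 in 3 others and 6.97, below every tumor, in day 7 replicate 3. Camera gave adjusted p = 0.00693 and 0.00416 (adjusted p = 0.764 and 0.639 with an estimated correlation).

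Genes of squamous differentiation were lower in WHIM30 suspensions. Of 23 members 6 fell and 1 rose at day 0, and 7 fell at day 7 (8 and 2, then 12 and 2 adjusted over the list alone; medians -2.65 and -3.13, or -2.43 and -2.92 with bounds). SPRR2A, a precursor of the cornified envelope with close paralogs, fell by -6.38 (SE 1.22, adjusted p = 0.0118) and -7.38 (SE 1.31), and involucrin, IVL, by -4.4 (SE 1.17, adjusted p = 0.0311) and -4.32. The camera test gave adjusted p = 1.32e-06 and 1.74e-08 (adjusted p = 0.676 and 0.554 with an estimated correlation), and without the 4 libraries no member was called. The list mean was 2.55 to 3.69 in the tumors, 2.06 and 1.87 in the replicate 1 suspensions and 0.53 to 0.56 in the 4 others. Outside the lists, CLCA2 fell by -2.67 (SE 0.51, adjusted p = 0.00682) and -3.24 (SE 0.53, adjusted p = 0.0082), and the tight junction protein CLDN1 by -2.64 (SE 0.58) at day 7. The axon guidance receptor ROBO1 rose by 6.11 and 6.1. The epithelial junction list, which parted the 4 libraries from the rest, had 2 called members at day 0 and 1 at day 7, all lower (2 and 1 adjusted over the list alone; medians -1.27 and -1.39, camera adjusted p = 6.11e-06 and 7.42e-07; adjusted p = 0.676 and 0.554 with an estimated correlation). In all, 2152 genes differed at day 0 (1177 higher, 975 lower) and 1100 at day 7 (733 higher, 367 lower). Without the 4 libraries, with the spread taken from other groups, 1776 and 240 genes were called, of which 675 and 79 were among the former. On WHIM30 libraries alone, where the spread between the replicates is not shared with WHIM2, only 5 and 2 genes were called, and on the compared groups alone 1160 and 0 (3173 at an unadjusted p under 0.05). Leaving out single libraries moved the counts from 442 (without day 0 replicate 3) to 6331 (without day 0 replicate 1), and from 18 (without tumor replicate 1) to 6421 (without day 7 replicate 1). Tumors ran in lane 5 and suspensions in lane 6, so lane and treatment cannot be told apart.

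Between day 7 and day 0 of WHIM30 edgeR called 0 genes and DESeq2 0. At an unadjusted p under 0.05 there were 957 of 18936 genes, close to the share of 0.05 that chance alone gives. The mouse as a block gave 0 again, with 1052 at an unadjusted p under 0.05. Without the 4 libraries 1 library is left on each side, which gives no test of this change.

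The WHIM2 brain metastasis, 1 library against 3 tumors, had lower heat shock genes. Of 18 members 6 were lower (8 adjusted over the list alone; median -1.02), HSPH1 by -2.01 (SE 0.24, adjusted p = 0.000366), CHORDC1 by -1.67, DNAJA1 by -1.28 and HSP90AA1 by -1.22. Genes of the amino acid response, induced when ATF4 is active, were higher for 3 of 21 members (8 adjusted over the list alone; median 0.41), DDIT3 by 1.81 (SE 0.33), SESN2 by 1.92 and ATF4 by 1.01. Camera gave adjusted p = 3.66e-07 and 0.000501, and neither was called with an estimated correlation (adjusted p = 0.999 for both with an estimated correlation). DLK1 stood at 589 CPM against 22.5 ± 17.9 in the tumors (4.71, SE 0.6, adjusted p = 0.000628), and TES, a focal adhesion protein, was higher by 4.62 (SE 0.37, adjusted p = 1.45e-05). The ceramide synthase CERS6 was lower by -5.41 (SE 0.59, adjusted p = 0.000149), the Wnt antagonist FRZB by -4.94 (SE 0.82), SAT1, an enzyme of polyamine breakdown, by -3.97 (SE 0.45; 6.26 against 98.4 ± 4.95 CPM) and the cell cycle kinase CDK6 by -3.46 (SE 0.77, adjusted p = 0.0169). In all, 1043 genes were called, 468 higher and 575 lower (44.9% higher, or 56.0% with upper quartile scaling). The lone library has no replicate, was assumed to vary like the other groups and ran in lane 6, so lane, library and site cannot be told apart. Without tumor replicate 1 the count was 584, without tumor replicate 2 it was 671, and without the 4 WHIM30 libraries, which share in the estimate of the spread, it was 3626.

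WHIM30 brain metastases (n = 2) had lower interferon-response genes than WHIM30 tumors (n = 3). Of 32 members 20 fell and none rose (31 fell when adjusted over the list alone; median -2.04). The RNA sensor DDX58 fell by -2.33 (SE 0.27), DDX60 by -2.11 and the antiviral enzyme RSAD2 by -3.56. IDO1, which interferon induces (chromosome 8, 39902275 to 39928444), fell from 247 ± 37.1 to 9.95 ± 0.596 CPM (-4.63, SE 0.57, adjusted p = 0.000612). Antigen-processing genes fell for 4 of 13 members (11 adjusted over the list alone; median -1.24), B2M by -1.56 (SE 0.41), and NF-kB and cytokine genes for 6 of 25 (9 adjusted over the list alone; median -1.6, -1.38 with bounds), BIRC3 by -2.86 (SE 0.51) and the chemokine CXCL8 by -3.76. Camera at the preset correlation gave adjusted p = 8.75e-35, 6.18e-09 and 5e-10 (adjusted p = 0.119, 0.62 and 0.108 with an estimated correlation). Without the 4 suspension libraries 31 interferon-response genes fell and the list was called with either correlation (adjusted p = 0.00109 with an estimated correlation). The list mean was 5.9 and 6.08 in the brain libraries and 8.06 to 8.32 in the tumors, while the fibroblast list stood at 3.22 and 8.22 against 5.53 to 6.29, and mouse transcripts took 78.9% and 18.9% against 8.02%.

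Other genes lower in WHIM30 brain metastases were CALCRL, a receptor of vasoactive peptides (47.3 ± 13.4 to 0.92 CPM; -5.37, SE 0.82, adjusted p = 0.00339), and the mannosidase MAN1A1 (-5.24, SE 0.48, adjusted p = 0.000156). Higher were FAM133A (1.72 to 38.9 ± 20.2 CPM; 4.5, SE 0.54, adjusted p = 0.000581), the matrix protein SPON2 (10.3 to 81.3 ± 26.8 CPM; 2.98, SE 0.47), the water channel AQP1 (2.68, SE 0.57, adjusted p = 0.0191) and the Wnt inhibitor APCDD1 (2.51, SE 0.34, adjusted p = 0.00121). In all, 798 genes differed, 342 higher and 456 lower. The count was 220 without tumor replicate 2, 248 without tumor replicate 1, 352 without tumor replicate 3, 2039 without brain replicate 1, 1876 without brain replicate 2 and 3493 without the 4 suspension libraries, with 794 of the 798 among the last. On WHIM30 libraries alone it was 20, and on the compared groups alone 35. The brain libraries ran in lanes 2 and 3 and the tumors in lane 5, so lane and site cannot be told apart.

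**Figure D3:**
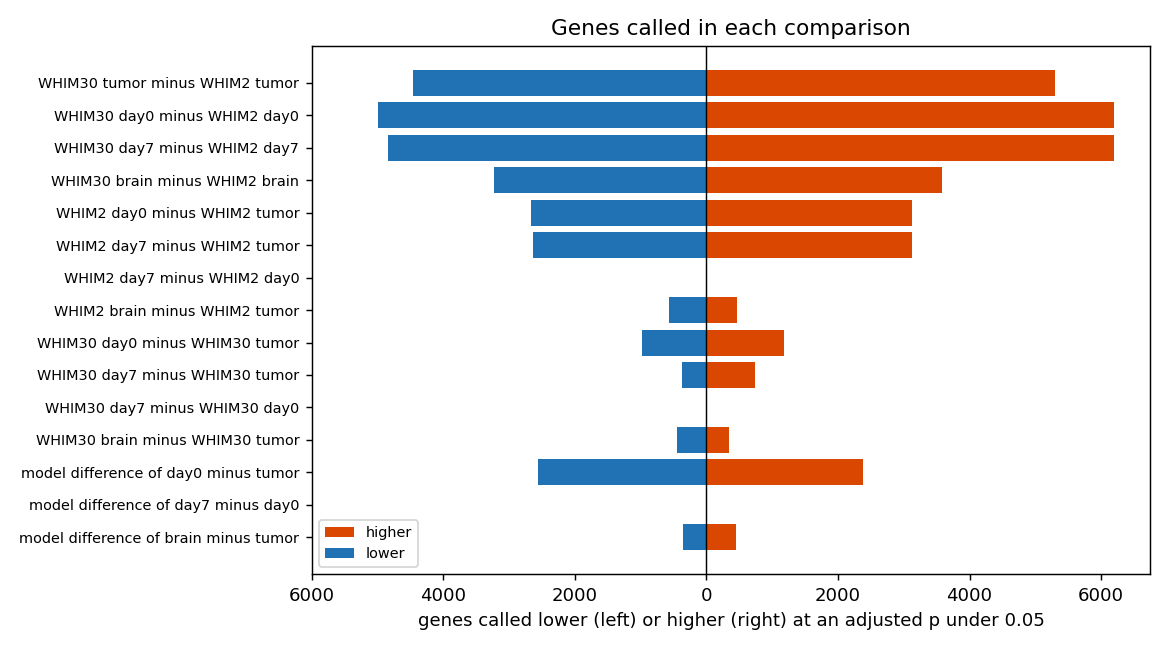
Bars give the number of genes called at an adjusted p under 0.05 (x axis), lower to the left in blue and higher to the right in orange, for the 12 comparisons of groups and the 3 differences between models (y axis). Calls range from 0 between day 7 and day 0 to 11186 between the models at day 0.

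Whether the models changed differently was tested as the difference of their changes. In WHIM2 the suspensions came from the mice of the tumors, and all but day 0 replicate 3 ran in lane 5. In WHIM30 they came from other mice than the tumors and ran in lane 6, against lane 5 for the tumors. Brain libraries ran in other lanes than tumors in both models. Lane and mouse therefore cannot be told apart from model in the differences from tumor to suspension or brain. From tumor to day 0 suspension, 4945 genes changed differently, 2376 with a higher and 2569 with a lower change in WHIM30 (48.0% higher, or 57.5% with upper quartile scaling). Without the 4 libraries the count was 5973 (44.2% higher). All 25 mitosis genes differed (25 adjusted over the list alone; median difference 4.2, NUSAP1 4.21, SE 0.19), as did all 24 replication genes (24 adjusted over the list alone; median 2.74). In WHIM30 itself 1 mitosis gene and 0 replication genes were called between day 0 and tumor. YAP targets differed for 8 of 17 members, all with a lower change in WHIM30 (9 adjusted over the list alone; median -2.58). These 3 lists were called with either correlation (camera adjusted p = 5.44e-78, 4.48e-34 and 1.78e-05; adjusted p = 0.00143, 0.0317 and 0.00584 with an estimated correlation), but without the 4 libraries only mitosis was (adjusted p = 0.0035, 0.107 and 0.0643 with an estimated correlation). The median differences stayed near their values then, at 3.63, 2.28 and -2.16, with only replicate 1 of the WHIM30 suspensions left. Between day 7 and day 0 no gene changed differently by edgeR, and 1 did by DESeq2. At an unadjusted p under 0.05 there were 309 of 18936, below the share of 0.05 that chance alone gives. The difference in the change from tumor to brain rests on 1 WHIM2 brain library. That library has no replicate and was assumed to vary like the other groups. The WHIM30 brain libraries differed by a BCV of 0.519, against 0.074 to 0.095 between WHIM30 tumors. From tumor to brain, 793 genes changed differently, 442 with a higher and 351 with a lower change in WHIM30 (55.7% higher, or 43.7% with upper quartile scaling). Heat shock genes differed for 6 of 18 members (7 adjusted over the list alone; median 1.07, camera adjusted p = 8.79e-07), interferon-response genes for 4 of 32 (8 adjusted over the list alone; median -2.06, adjusted p = 5.54e-09) and NF-kB genes for 4 of 25 (6 adjusted over the list alone; median -1.6, adjusted p = 2.83e-06), none called with an estimated correlation (adjusted p = 0.92, 0.92 and 0.843 with an estimated correlation). Leaving out single libraries moved the 793 from 406 (without WHIM30 tumor replicate 2) to 1783 (without WHIM30 brain replicate 1).

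Calls shared by the models were few. From tumor to day 0, 216 genes were higher in both models where 193.8 would be shared by independent sets (Fisher's exact test, one-sided, p = 0.0405, adjusted p = 0.0694 over 12 tests), and 125 were lower in both against 137.1 (adjusted p = 0.965). More changed in opposite directions, 293 higher in WHIM2 and lower in WHIM30 and 195 the reverse. From tumor to day 7, 170 were higher in both against 120.8 (exact p = 1.09e-06, adjusted p = 4.36e-06) and 55 lower against 51.2 (adjusted p = 0.403), while 114 and 92 changed in opposite directions. From tumor to brain, 27 were higher in both against 8.5 (exact p = 1.23e-07, adjusted p = 7.38e-07) and 31 lower against 13.8 (exact p = 2.71e-05, adjusted p = 8.13e-05), while 18 and 19 changed in opposite directions. With an absolute log2 fold change of at least 1 in both models 2 of these calls changed, since 82 genes were then higher in both at day 0 against 58.4 (exact p = 0.000986, adjusted p = 0.00237) and 5 in brain against 2 (exact p = 0.0531, adjusted p = 0.0796). Opposite changes then no longer outnumbered shared ones at day 0 (39 and 41 opposite, 82 and 10 shared). The exact tests treat genes as independent, which they are not. Calls of both models also came from the same fit, so genes with little spread can be called in both whatever their direction. No expected number was computed for opposite changes. Across all genes the log2 fold changes of the models correlated at -0.016 for day 0, 0.014 for day 7 and 0.025 for brain (Pearson).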

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

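The tests of technical explanations and the counts of other splits in this part were chosen after the results were seen, while the differences between the models were planned.

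The change from tumor to day 0 suspension differed between the models, by the test of the difference, for 4945 genes, and that from tumor to brain for 793. Within WHIM30 lane and source mouse changed along with these steps, so they cannot be told apart from model here. For day 0 the median differences of log2 fold change (WHIM30 minus WHIM2) were 4.2 for mitosis, 2.74 for DNA replication, 1.77 for immediate early and 1.72 for mitochondrial genome genes. They were -1.91 for interferon-response, -1.42 for antigen-processing, -1.91 for NF-kB, -2.75 for basal keratin and adhesion, -1.55 for mature luminal, -3.15 for luminal progenitor, -1.95 for epithelial junction, -5.04 for squamous differentiation and -2.58 for YAP target genes. For brain they were 1.07 for heat shock, -2.06 for interferon-response and -1.6 for NF-kB genes. The brain values, like the count for brain, rest on 1 WHIM2 brain library without a replicate. Of these lists mitosis, replication and YAP targets at day 0 were called with an estimated correlation, and the others with the preset correlation alone. The 4 WHIM30 suspension libraries described below weigh on the day 0 values. Without them replication and YAP targets lost the call with an estimated correlation. The median differences of both lists stayed near the values above, with only replicate 1 of the WHIM30 suspensions left at day 0. The medians were then 3.63 for mitosis, -1.74 for luminal progenitor, -0.61 for epithelial junction and -3.88 for squamous differentiation genes, and antigen-processing, mature luminal, squamous differentiation and mitochondrial genome genes were no longer called.

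Mouse transcripts, which no comparison uses, exceeded the share of every mammary tumor of the same model in 9 libraries. They took 44.9% of counts in the WHIM2 brain metastasis, 12.7%, 18.0% and 18.6% in WHIM30 day 0 replicates 1 to 3, 12.4%, 14.4% and 30.9% in day 7 replicates 1 to 3, and 78.9% and 18.9% in WHIM30 brain replicates 1 and 2.

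The WHIM30 suspension libraries of 2 host mice had low epithelial and high mesenchymal and fibroblast lists. Mouse transcripts counted as human genes cannot account for the low epithelial junction list. It fell by at least 4.13 below the lowest tumor, and counts equal in number to the mouse counts would lower it by at most 0.53. Whether such counts raised the mesenchymal and fibroblast lists was not tested. Lane number alone cannot account for the low epithelial list, since 2 of the 6 suspension libraries with that number kept the tumor level. A swap with WHIM2 libraries cannot either, since all 4 correlated better with every WHIM30 tumor than with any WHIM2 tumor. Other human cells in place of the epithelial tumor cells remain open, as does a change of state of the tumor cells. The fibroblast list stood at 7.29 or more in all 4 libraries, which both would show, and no value at hand separates them. Nor was it tested whether the day 0 libraries of these 2 mice, with a BCV of 0.045 between them, came from one pool.

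The WHIM2 suspension libraries were alike at day 0 and day 7, both with low mitosis genes. Lane number cannot account for the low mitosis genes, whose median log2 fold change between day 7 and tumor within 1 lane number was -4.03. Whether these libraries shared a sequencing run was not checked. Whether the libraries of both times came from one pool or one time point remains open. In lane 5 the median BCV was 0.03 between libraries of different mice (8 pairs) and 0.028 between those of one mouse (2 pairs), a ratio of 1.09. That cannot decide it, since WHIM2 libraries carried no mark of their mouse. Deviations of suspensions and tumors correlated at -0.023 to 0.048 within a mouse and at -0.053 to 0.028 between mice. Day 0 replicate 3, which ran in lane 6, differed from the lane 5 suspensions by a BCV of 0.088 to 0.104. A culture that settles into one state, or a change during the processing of the tumor itself, was not tested.

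Interferon-response genes were lower in WHIM30 brain metastases than in WHIM30 tumors. Mouse transcripts counted as human genes cannot account for this, since the epithelial junction list fell by at most 0.18 in these libraries while the interferon list fell by 2.16 and 1.98. One shift in the share of fibroblast-type cells, common to both brain libraries, cannot either. In them 31 and 32 of 32 members lay below every tumor. The fibroblast list, by contrast, lay below the tumors in 1 library and above them in the other. A separate shift of cell share in each library remains open. In the 4 WHIM30 suspension libraries with a high fibroblast list the interferon list mean, 6.02 to 7.56, also lay below every tumor (8.06 to 8.32). Lane and site cannot be told apart, since 0 of the tumor libraries ran in the lanes of the brain libraries, and the biological explanation, a different environment or selected tumor cells in the brain, remains untested.

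Other splits of the same libraries were counted for each comparison of at least 3 libraries a group. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real splits gave 9764 calls between tumors, 11186 between day 0 and 11039 between day 7 suspensions of the models, 5781 and 5762 in WHIM2 day 0 and day 7 against tumor, and 2152 and 1100 in WHIM30 day 0 and day 7 against tumor. In each of these 1 of 10 splits, the real one, gave as many calls, and the highest of the others gave 0. For WHIM2 day 7 against day 0 the real split and all 10 splits gave 0. For WHIM30 day 7 against day 0 the real split gave 0, which any split reaches, and the highest of the others gave 3968. That points to a structure of the samples, replicate 1 against the 4 libraries of the other 2 mice, and among the 4 splits that part the libraries of every mouse, the real one included, the highest other value was 0. The difference between the models in the change from tumor to day 0 was set against 100 drawn splits. Of these 1, the real one with 4945, gave as many, and the highest other gave 4210. The draws regrouped both models at once and took no account of shared mice. A low share can therefore come from the WHIM2 change alone, and chance is not excluded for a difference between the models. For the difference in the change from day 0 to day 7 the highest other split gave 1092. The real value is 0, which any split reaches, so the count tests nothing there.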

How the results depend on the processing

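The fits without 4 WHIM30 libraries, on one model alone, within a lane and on the libraries of the block fits without a block were chosen after the data were seen, as were all settings for the shared calls except the fold limit, and the rest before. Counts between the models in tumors, at day 7 and in brain, and the difference at day 0, stayed within 1.5 times of the reported value in every fit run. WHIM30 counts within the model are the least stable. The causes of the shifts were not tested, except where fewer calls follow from a stricter criterion. With an absolute log2 fold change of at least 1, the calls against tumor were 3374 (WHIM2 day 0), 3341 (WHIM2 day 7), 814 (WHIM30 day 0), 529 (WHIM30 day 7) and 412 (WHIM30 brain). DESeq2 called 3 genes for WHIM2 day 7 against day 0, 1832 for WHIM2 brain, 3499, 2690 and 1496 for WHIM30 day 0, day 7 and brain, and for the differences between models 1 (day 7 against day 0) and 1416 (brain). With no filter beyond 1 count the calls were 541 for WHIM2 brain, 1121, 311 and 344 for WHIM30 day 0, day 7 and brain, and 338 for the difference in brain. With an offset for effective length they were 1202, 474 and 515 for WHIM30 day 0, day 7 and brain, and 477 for the difference in brain. Without the 4 WHIM30 libraries the calls were 8674 for WHIM2 day 0, 3626 for WHIM2 brain, 240 for WHIM30 day 7, 2 for WHIM30 day 7 against day 0 (1 library a side, no test of that change), 3493 for WHIM30 brain and 3299 for the difference in brain. On the compared groups alone they were 9573, 10090 and 4272 for WHIM2 day 0, day 7 and brain, and 1160, 0 (3173 at an unadjusted p under 0.05) and 35 for WHIM30. On one model alone they were 10749, 10694 and 6745 for WHIM2, and 5, 2 and 20 for WHIM30. Lane 6 alone gave 7100 at day 0 between the models. With the mouse as a replicate block, on the libraries that share mice, they were 10332 and 10310 for WHIM2 day 0 and day 7, and on the same libraries without the block 10319 and 10293, so the rise came with the set of libraries. The other counts stayed at 0 in both. Leaving out single libraries gave 8409 to 8569 between tumors, 9892 to 11903 at day 0, 9649 to 11854 at day 7 and 5630 to 7569 in brain between the models. It gave 4478 to 4660 and 4418 to 4591 for WHIM2 day 0 and day 7, 584 to 733 for WHIM2 brain, 442 to 6331 for WHIM30 day 0, 18 to 6421 for WHIM30 day 7 and 220 to 2039 for WHIM30 brain. The differences between the models gave 3868 to 6757 (day 0) and 406 to 1783 (brain), and the comparisons of day 7 with day 0 gave 0 throughout. The lone WHIM2 brain library could not be left out. Of 137 list tests called with the preset correlation 9 were called with an estimated one, and in the 5 comparisons that share mice 33 list tests were called over all libraries, 52 in the block fits and 49 on the same libraries without the block. Shared calls of the models (341, 225 and 58 for day 0, day 7 and brain) were 92, 97 and 19 with an absolute log2 fold change of at least 1, 636, 587 and 165 with DESeq2, 140, 62 and 18 without the filter, and 163, 96 and 32 with the length offset. They were 83 at day 7 and 465 in brain without the 4 libraries, and 3, 2 and 5 on one model alone. The 146 pairs of a named gene and a comparison were chosen from calls on these same libraries, so a kept direction is little support. For these pairs 2346 values were computed under other fits. The direction was kept in all, and 123 values were no longer called (28 on one model alone, 21 on the compared groups alone, 10 without the 4 libraries and 53 with single libraries left out).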

Other observations

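Some genes of hormone response, drug transport and oxygen supply differed between WHIM2 suspensions and tumors, while their lists were called in part of the tests or not at all. Among 18 mature luminal genes 4 rose at day 0 and 3 at day 7 (4 and 3 adjusted over the list alone; medians 0.63 and 0.57, camera adjusted p = 0.0446 and 0.0423; adjusted p = 0.394 and 0.411 with an estimated correlation). They included the estrogen receptor gene ESR1, from 0.304 ± 0.0832 to 2.13 ± 0.325 CPM at day 0 (log2 fold change 2.78, SE 0.46, adjusted p = 0.000303), a low level, and TBC1D9 (2.39, SE 0.13). Of 11 drug efflux genes 3 rose and 2 fell at day 0, and the list was not called by camera (adjusted p = 0.306), while fry, which does not compare the list with other genes, gave adjusted p = 0.00057. MVP, the major vault protein, rose from 1.32 ± 0.287 to 54.2 ± 7.08 CPM (5.35, SE 0.22, adjusted p = 4.05e-10), and the efflux pump ABCG2 fell from 17.8 ± 4.08 to 2.94 ± 0.366 CPM (-2.59, SE 0.47). Hypoxia and glycolysis genes fell for 8 of 24 members and rose for 2 at day 0 (9 and 2 adjusted over the list alone; median -0.75). The carbonic anhydrase CA9 fell from 22.5 ± 10.8 to 0.771 ± 0.244 CPM (-4.86, SE 0.93, adjusted p = 0.000936) and the kinase PDK1 by -1.9 (SE 0.25). That list was not called in the fit over all libraries (camera adjusted p = 0.171, fry 0.192). It was called in a fit on the WHIM2 tumor and suspension libraries alone, with the mouse as a block or without (camera adjusted p = 0.00191 and 0.00633; adjusted p = 0.597 and 0.657 with an estimated correlation).

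Growth factor receptors rose in WHIM2 suspensions for 9 of 26 members at day 0 and fell for 1 (10 and 1 adjusted over the list alone; median 0.69, 0.62 with bounds), among them MET, from 0.378 ± 0.076 to 9.97 ± 1.23 CPM (4.69, SE 0.61, adjusted p = 2.95e-05), and EGFR (1.53, SE 0.22). Over all libraries camera did not call the list (adjusted p = 0.0874) and fry did (0.000215). On the WHIM2 tumor and suspension libraries alone camera called it with the block and without (adjusted p = 0.0018 and 0.00236; adjusted p = 0.162 and 0.059 with an estimated correlation). From the macrophage and microglia list, genes that tumor cells can also express, 4 of 11 rose and 1 fell (4 and 1 adjusted over the list alone), the lysosomal protease CTSS from 0.292 ± 0.171 to 14.6 ± 2.18 CPM (5.56, SE 0.48) and CD68 to 3.01 ± 0.369 CPM (6.44, SE 1.12). Here too camera did not call the list over all libraries (adjusted p = 0.197) and fry did (2.6e-05). On the smaller set of libraries, which kept 5 members, camera called it with the block and without (adjusted p = 0.0105 and 0.0144; adjusted p = 0.187 and 0.119 with an estimated correlation). In WHIM30 suspensions day 7 against day 0 had no called gene, but camera at the preset correlation called hypoxia and glycolysis genes higher (median 0.49, adjusted p = 5.87e-10) and mitochondrial genome genes lower (median -0.74, adjusted p = 3.09e-07). Neither was called with an estimated correlation (adjusted p = 0.451 and 0.979 with an estimated correlation). The rise of hypoxia genes lay in the 2 host mice that stood apart, with list means from 5.37 to 5.97 and from 5.4 to 6.69, against 6.61 and 6.62 in replicate 1. The mean of the mitochondrial genome list fell in all 3 mice, from 10.2 to 9.88, from 11.27 to 10.8 and from 11.97 to 10.83. With the mouse as a block both lists were again called at the preset correlation alone (camera adjusted p = 1.97e-10 and 1.05e-11; adjusted p = 0.759 for each with an estimated correlation).

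Fatty acid synthesis genes were lower in WHIM30 than in WHIM2, for 7 of 15 members in tumors and for 9 with 1 higher in suspensions of either day (6 in tumors, and 9 and 1 in suspensions, adjusted over the list alone; medians -0.77 in tumors, -1.33 at day 0 and -1.49 at day 7). Camera gave adjusted p = 0.0289, 0.00168 and 0.00382 (adjusted p = 0.537, 0.319 and 0.423 with an estimated correlation). Amino acid response genes were higher in WHIM30 tumors for 15 of 21 members (15 higher and 1 lower adjusted over the list alone; median 1.18, camera adjusted p = 0.0046; adjusted p = 0.636 with an estimated correlation). Counts of the mitochondrial genome took 15.1 to 23.7% of human counts in WHIM2 tumors and 2.5 to 2.7% in WHIM30 tumors.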
